A study of Homo sapiens with 8 samples.

How the data were processed

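Peripheral blood cells of 4 patients with chronic pruritus of unknown origin (CPUO) and 4 healthy controls (HC) were profiled by droplet single-cell RNA sequencing, with 1 library per donor. Per the labels' protocols, red cells were lysed, the cells had to pass a viability threshold, and libraries were made with 10x Genomics 3′ v3 chemistry with an aim of 8000 cells each. The files hold 6644 to 14218 barcodes per library. The deposited matrices hold raw UMI counts per gene and barcode, per the file headers and the values themselves, which are whole numbers. The submitters' processing notes name bcl2fastq 5.0.1, Cell Ranger 8.0.1, Seurat 5.1.0 and the GRCh38 build. The matrix headers name Cell Ranger 8.0.1 for 5 libraries (CPUO 1 to 3, HC 1 and HC 2) and Cell Ranger 9.0.1 for 3 (CPUO 4, HC 3 and HC 4), and these sets were also deposited apart. They are called the 8.0.1 block and the 9.0.1 block here. All 62700 gene identifiers are alike in the 8 libraries, and all 62700 matched the reference table of gene names. The deposit holds no cell annotation.

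Barcodes with under 200 genes or over 20% mitochondrial UMIs were left out (1042). Doublets were scored with Scrublet in each library, and the highest-scoring 0.8% per 1000 barcodes were left out (6014, or 5.31% to 11.4% per library), which left 68724 cells, 33198 of CPUO and 35526 of HC donors. Counts were scaled to 10000 per cell and log-transformed. With scanpy 1.11.5 and numpy 2.4.6 under Python 3.11.15, 2000 variable genes gave 30 principal components, which were corrected for library with a Harmony-type method. Cells were joined to 20 neighbours and clustered with the Leiden method at resolution 1, which gave 22 clusters. Clusters were named from fixed marker genes, and each name stands for cells like that type, so that shares may differ from the authors' own for reasons of naming. The 18 named clusters form 10 classes, and 4 clusters (3502 cells) stayed unnamed for too few markers, 1 of them led by the cell cycle genes MKI67 and TOP2A. Unnamed cells made up 3.46% ± 1.91 (SD, n = 4) of kept CPUO cells and 5.87% ± 3.78 (n = 4) of HC cells. Plasma cells formed no cluster of their own among the 22, but did with doublets kept and without correction for library. B and plasma cells were joined as B lineage after the data were examined. Of the plasma cells found with doublets kept, 192 lay in the B lineage of HC 3, or 17.0% of it, against at most 0.269% in any other library. HC values of this class thus carry the plasma cells of 1 library. Without correction, a cluster with IGHA2, JCHAIN and MZB1 among its leading genes held 568 cells, 549 of them in HC 3, so the 17.0% may be too low. In CD4 T cells, cluster 1 (led by TSHZ2, CCR7 and LEF1) was the largest in CPUO, with 47.5% of pooled cells. In HC it was cluster 0 (AQP3, CD40LG and IL7R), with 49.3%. CPUO cells were split almost evenly: CPUO 1 to 4 had 1318, 484, 1325 and 893 cells in cluster 1 and 1086, 842, 998 and 1090 in cluster 0. In the B lineage, 64.5% of pooled CPUO cells lay in cluster 8 (TCL1A and IGHD) and 55.8% of pooled HC cells in cluster 9 (IGHG2 and TNFRSF13B). HC 3 gave 791 cells of cluster 9, against 192, 238 and 152 in HC 1, 2 and 4, where cluster 8 held 200, 250 and 302. No cluster of neutrophils, eosinophils or basophils was found.

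Donors, not cells, were the replicates. Counts were summed per library and class, and a library entered with at least 20 cells of the class, which 8 classes met. CPUO and HC were compared with edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr, two-sided, Benjamini-Hochberg threshold 0.05) under R 4.3.3. Whole libraries, summed over all kept cells, were compared in the same way. Levels are given as CPM (counts scaled to a common sum per library) with SD, and fold changes as log2 of CPUO over HC with SE. Class shares were compared with exact two-sided permutation tests over all 70 assignments, whose smallest p is 0.0286, and over the 30 assignments within the blocks, whose smallest p is 0.0333. Intervals on shares are exact 95% binomial intervals, and they cover counting error only.

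Before the data were examined, the tests, the marker genes, 26 gene lists, the rule for the genes to name and most alternatives were fixed. The lists cover inflammatory chemokines with CCL3, chemokine receptors, itch mediators and type 2 immunity, NF-kB and TNF response, immediate early genes, interferon response, interferon gamma and MHC class II, cytotoxic effectors, naive T cells, T cell activation, JAK-STAT feedback, glucocorticoid response, calgranulins and inflammasome, heat shock and unfolded protein, hypoxia and glycolysis, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, p53 and apoptosis, cell cycle, and transcripts of 6 other cell types (neutrophil, monocyte, red cell, platelet, B and plasma, T and NK). Lists were tested per class with camera in limma 3.58.1, on voom values with a preset correlation of 0.01, and adjusted over 179 tests. At least 5 members had to be measured, so 24 lists were tested, and red cell and platelet transcripts were tested in no class. Of the immediate early genes, 3 are also in the glucocorticoid list and 1 in the NF-kB list, and 4 chemokines are also in the NF-kB list.

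Genes were named by the rule that, where no gene passed, takes the 2 genes of smallest p in each direction per class, plus up to 4 members of smallest p from each list that passed, and 14 fixed itch and chemokine genes where their mean reached 10 CPM, with HDC, the histamine-forming enzyme, too low to be tested in any class. Where a gene had passed, the rule would have taken those past the threshold whose groups lie apart. Genes of the HLA, immunoglobulin, T cell receptor and KIR families, and sex-linked marker genes, were not named, and a few results for genes that the rule names are not reported here. For the share of cells with a CCL3 UMI, each cell was also thinned to 1000 UMIs. Alternatives were DESeq2 1.42.0, other size factors, no filter on low counts, no removal of doublets, a stricter cell filter (500 genes, 10% mitochondrial UMIs), clusters without correction, each library left out, the block as a covariate, the replicate number as a block, an estimated correlation, and fry. After the data were examined, a common floor of 3038 UMIs per cell, the 8.0.1 block alone, and the libraries without CPUO 1 and CPUO 2 were added.

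The gene test was tested on simulated data with the real means and library sizes. The simulated libraries varied independently, without the blocks of the real data, and how the blocks change the recovery was not tested. Of genes changed 4-fold, it recovered 47.8% in CD4 T cells (14354 genes tested), 35.5% in CD8 T cells (13350), 43.8% in NK cells (13124), 69.6% in innate-like T cells (9902), 52.6% in the B lineage (11008), 46.5% in classical monocytes (12434), 62.6% in non-classical monocytes (9239), 58.9% in dendritic cells (8769) and 22.9% in whole libraries (20505). Of genes changed 2-fold it recovered at most 7.2%, in non-classical monocytes.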

Results

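Gene expression was measured in single blood cells of 4 patients with chronic pruritus of unknown origin (CPUO), a lasting itch with no identified cause, and of 4 healthy controls (HC). The labels state that the controls were matched, but not which control belongs to which patient. The 8 libraries hold 75757 barcodes and 358239296 UMIs (unique molecular identifiers, which count RNA molecules). Total counts were 41122082, 40319312, 40314780 and 49849946 UMIs in CPUO 1 to 4, and 32841498, 49960539, 50262337 and 53568802 UMIs in HC 1 to 4. The median per barcode was 4479, 3955, 3696 and 4372 UMIs in CPUO 1 to 4, and 4178, 4219, 2567 and 5819 UMIs in HC 1 to 4. The shallowest barcode had 3038 UMIs in CPUO 1 and 2720 in CPUO 2, against 500 to 502 in the other 6 libraries. The 8.0.1 block holds 3 CPUO and 2 HC libraries, and the 9.0.1 block holds 1 CPUO and 2 HC libraries. The first principal component of expression separated these blocks in each class and in whole libraries, with 68.1% to 78.8% of the variance.

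The first comparison asks whether the makeup of blood cells differed. Classical monocytes, the CD14-positive phagocytes of blood, made up 6.92% ± 6.23 (SD, n = 4) of classed cells in CPUO and 19.1% ± 5.26 (n = 4) in HC blood. NK cells, cytotoxic lymphocytes without a T cell receptor, made up 25.9% ± 7.14 of CPUO cells and 14.1% ± 4.34 of HC cells (SD, n = 4 each). Platelets made up 0.242% ± 0.105 of CPUO and 0.972% ± 0.451 of HC barcodes (SD, n = 4 each), and each CPUO library lay below each HC library. CD8 T cells made up 22.9% ± 5.92 and 16.2% ± 5.40, and CD4 T cells 26.6% ± 7.15 and 32.6% ± 12.2 (SD, n = 4 each). The exact permutation p was 0.0286 for platelets and 0.0571 for classical monocytes and for NK cells, and after adjustment over 10 classes each of these was 0.190, so no share passed. With edgeR on cell counts, platelets passed (log2 fold change -2.01, adjusted p = 0.00528), and classical monocytes (-1.46, adjusted p = 0.0938) and NK cells (0.88, adjusted p = 0.164) did not.

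The other shares did not pass either. Non-classical monocytes, which patrol vessel walls and carry FCGR3A, made up 2.11% ± 0.715 in CPUO and 3.80% ± 1.66 in HC blood (exact permutation p = 0.114, SD, n = 4 each). B lineage cells made up 7.84% ± 2.05 and 7.12% ± 2.06, and innate-like T cells, which include MAIT and gamma delta T cells, 6.08% ± 4.14 and 4.36% ± 1.66. Dendritic cells made up 1.07% ± 0.610 and 1.43% ± 0.407, and plasmacytoid dendritic cells 0.271% ± 0.299 and 0.385% ± 0.192. Within the 8.0.1 block, classical monocytes were at 4.17% in CPUO and 23.1% in HC blood, NK cells at 25.9% and 16.1%, and platelets at 0.279% and 1.30%. Within the 9.0.1 block, classical monocytes were at 15.2% and 15.0%, so their difference did not hold there, while NK cells were at 25.9% and 12.1% and platelets at 0.130% and 0.642%. CD8 T cells were at 25.1% and 20.7% in the 8.0.1 block and at 16.4% and 11.6% in the 9.0.1 block. CD4 T cells went opposite ways, with 27.3% and 23.1% in the 8.0.1 block and 24.6% and 42.2% in the 9.0.1 block. CPUO 1 held 85 classical monocytes, or 1.17% of its classed cells (95% exact interval 0.934% to 1.44%).

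**Figure D1:**
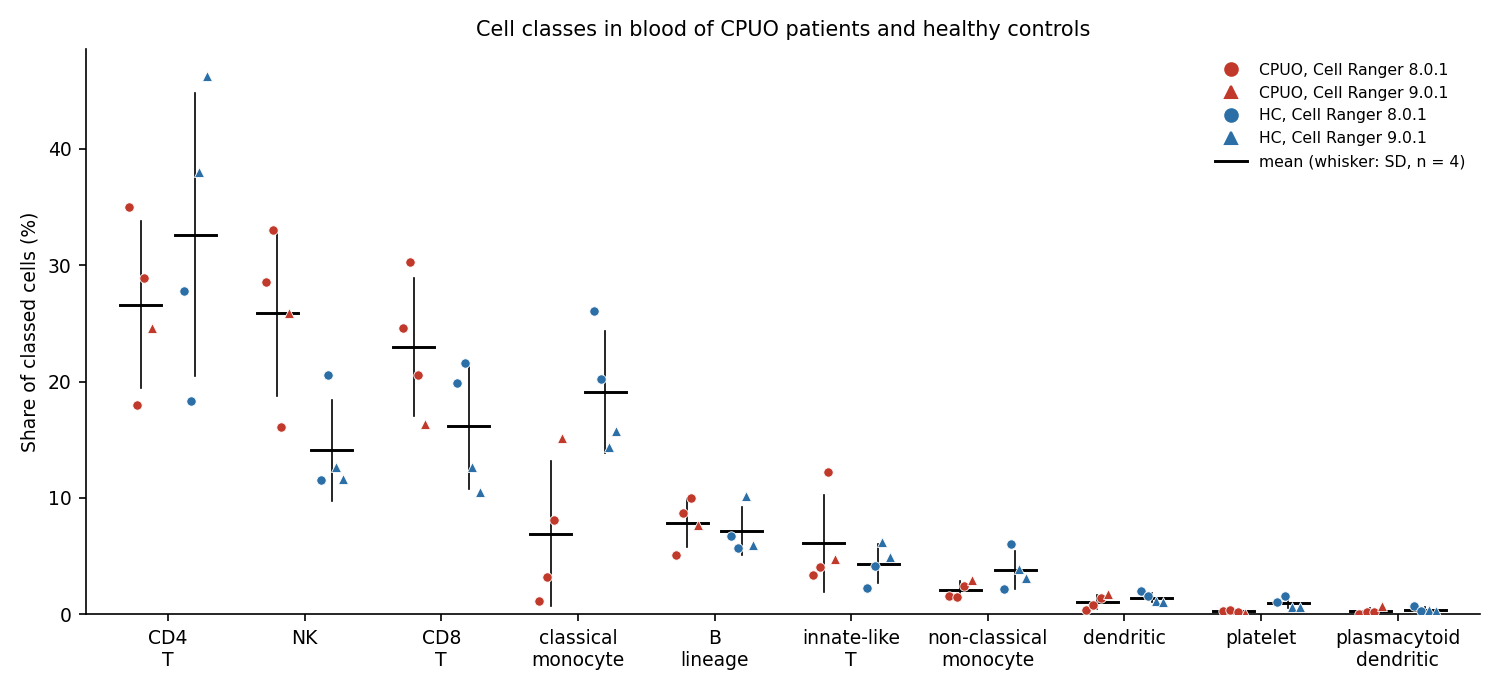
Share of classed cells (%, y axis) in each of 10 cell classes (x axis), with 1 point per library, red for CPUO and blue for HC, circles and triangles for the Cell Ranger version, bars for the mean and whiskers for the SD (n = 4). NK cells average 25.9% in CPUO and 14.1% in HC blood, and classical monocytes 6.92% and 19.1%.

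The next comparison asks which genes differed within each class, and it opens with CCL3, the chemokine named in the series title, which recruits monocytes and lymphocytes. CCL3 (ENSG00000277632) lies on chromosome 17 of GRCh38, at 36088256 to 36090169 on the minus strand. In classical monocytes it stood at 668 ± 872 CPM in CPUO and 64.9 ± 31.4 CPM in HC blood (SD, n = 4 each), a log2 fold change of 3.36 (SE 0.90), with each CPUO library above each HC library (exact permutation p = 0.0286). In dendritic cells it stood at 195 ± 222 and 22.0 ± 8.71 CPM (log2 fold change 3.11, SE 0.81), again without overlap (exact permutation p = 0.0286). In NK cells, the lymphocytes with the highest level, it stood at 112 ± 62.9 and 61.8 ± 32.3 CPM (0.87, SE 0.51), and in CD8 T cells at 33.2 ± 34.7 and 11.2 ± 6.88 CPM (1.57, SE 0.81, and 0.65 without CPUO 2). Over all genes, the adjusted p by edgeR was 0.735 in classical monocytes, 0.816 in dendritic cells, 0.803 in NK cells and 0.883 in CD8 T cells, so CCL3 passed in none of these. Adjusted over the list alone, it passed by edgeR in classical monocytes (adjusted p = 0.0242, 10 chemokines) and in dendritic cells (adjusted p = 0.0211, 6 chemokines). DESeq2 called it in classical monocytes (log2 fold change 3.35, adjusted p = 0.0131) and in dendritic cells (3.14, adjusted p = 0.0110).

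CCL3 was lower in the remaining classes, at 25.3 ± 17.4 CPM in CPUO and 9.61 ± 7.46 CPM in HC non-classical monocytes (1.499, SE 0.63), and at 2.11 ± 1.04 and 0.666 ± 0.613 CPM in CD4 T cells (1.80, SE 0.67). It was not tested in innate-like T cells, where counts were too low. In the B lineage, taken here as the background for CCL3, it stood at 6.45 ± 3.81 and 3.09 ± 2.98 CPM, so the level in CD4 T cells lay below that background. Whether B lineage cells make some CCL3 themselves was not tested. Over whole libraries CCL3 stood at 84.1 ± 59.1 and 27.8 ± 18.0 CPM (1.60, SE 0.65, adjusted p = 0.564). Within the 8.0.1 block, CCL3 in classical monocytes averaged 751 CPM in CPUO and 87.7 CPM in HC blood, and within the 9.0.1 block 418 and 42.1 CPM. In dendritic cells it averaged 248 and 27.2 CPM in the 8.0.1 block and 38.0 and 16.8 CPM in the 9.0.1 block. In NK cells these were 121 and 83.9 CPM, and 84.0 and 39.8 CPM. In non-classical monocytes they were 16.7 and 15.5 CPM in the 8.0.1 block (log2 fold change 0.20, SE 0.35) and 51.1 and 3.74 CPM in the 9.0.1 block, and without CPUO 4 the log2 fold change there was 0.86. With the block as a covariate, the log2 fold change in classical monocytes was 3.17 (SE 0.73, adjusted p = 0.0976). CPUO 2 stood at 1961 CPM in classical monocytes and 513 CPM in dendritic cells, and without it the log2 fold change was 1.87 (SE 0.57, adjusted p = 0.9997) in classical monocytes and 1.94 (SE 0.60, adjusted p = 0.998) in dendritic cells. The difference between the effect in classical monocytes and that in each of 6 other classes did not pass (exact permutation, smallest adjusted p = 0.286).

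Cells with at least 1 CCL3 UMI made up 37.7% ± 19.7 of classical monocytes in CPUO and 17.7% ± 9.15 in HC blood (SD, n = 4 each, exact permutation p = 0.143). In the B lineage this background share was 1.71% ± 0.752 and 1.19% ± 0.997, at median depths of 4255 and 3997 UMIs, against 5292 and 6342 UMIs in classical monocytes. Thinned to 1000 UMIs, the shares were 21.3% ± 17.7 and 5.14% ± 2.42 of classical monocytes (exact permutation p = 0.0857), and 0.498% ± 0.219 and 0.235% ± 0.209 of B lineage cells. Thinning left out 4 CPUO and 48 HC classical monocytes, and 18 CPUO and 168 HC B lineage cells. In dendritic cells the shares were 33.6% ± 19.7 and 10.4% ± 4.95 before thinning (exact permutation p = 0.0571) and 10.5% ± 13.1 and 1.88% ± 1.70 after it (exact permutation p = 0.314).

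**Figure D2:**
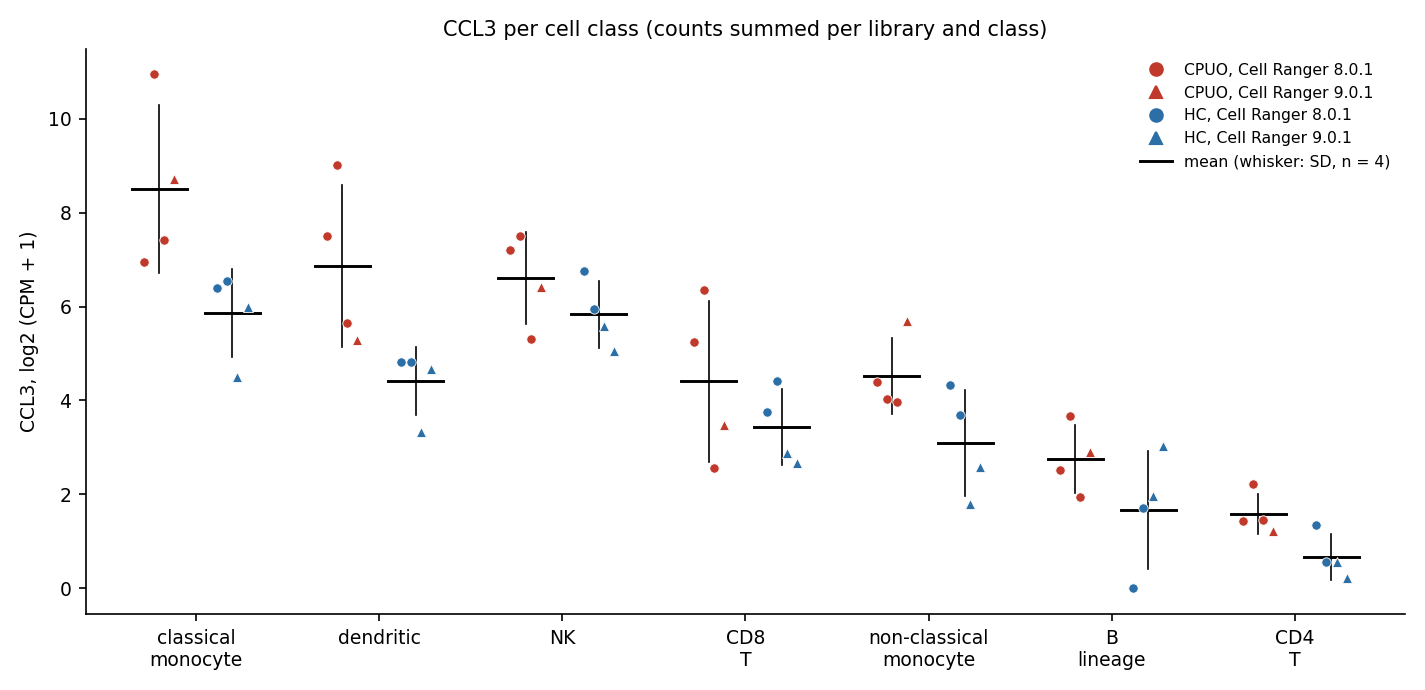
CCL3 as log2 (CPM + 1) (y axis) from counts summed per library and cell class (x axis), with 1 point per library, red for CPUO and blue for HC, circles and triangles for the Cell Ranger version, bars for the mean and whiskers for the SD (n = 4). In classical monocytes and dendritic cells each CPUO library lies above each HC library, and CPUO 2 is the highest at 1961 CPM in classical monocytes.

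Among the genes named in classical monocytes, G0S2, an inhibitor of fat breakdown (chromosome 1, 209675420 to 209676388), stood at 42.3 ± 21.0 CPM in CPUO and 2.46 ± 1.99 CPM in HC blood (log2 fold change 4.10, SE 0.62, n = 4 each). OSM, a cytokine of the IL-6 family that acts on sensory neurons and skin and was in the fixed set of itch genes (chromosome 22, 30262829 to 30266840), stood at 25.8 ± 25.2 and 0.714 ± 0.486 CPM (5.14, SE 0.88). IL1B, the inflammasome cytokine, had a log2 fold change of 2.90 (SE 0.77), and CD36, a scavenger receptor, one of -0.85 (SE 0.20). With edgeR none passed: the adjusted p was 0.421 for G0S2 and OSM, 0.735 for IL1B and 0.694 for CD36. With the block as a covariate, the adjusted p was 0.0065 for both G0S2 and OSM.

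In dendritic cells, NR4A3, a nuclear receptor induced by stimulation, stood at 72.4 ± 88.7 CPM in CPUO and 1.88 ± 1.60 CPM in HC blood (log2 fold change 5.18, SE 1.05, n = 4 each). PTGER4, a prostaglandin E2 receptor, had a log2 fold change of 1.59 (SE 0.29), and SMAD2, a TGF-beta signal carrier, one of -0.92 (SE 0.19). In non-classical monocytes HES1, a Notch target, had a log2 fold change of 1.72 (SE 0.30), and CMKLR1, the chemerin receptor, one of -1.72 (SE 0.37). With edgeR the adjusted p was 0.816 for each of these dendritic genes and 0.892 for both monocyte genes. With the block as a covariate, the adjusted p was 0.00982 for NR4A3, 0.0345 for PTGER4 and 0.0455 for SMAD2 in dendritic cells, and 0.168 for HES1 and for CMKLR1 in non-classical monocytes.

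In innate-like T cells, CXCR3, a receptor for interferon-induced chemokines (chromosome X, 71615916 to 71618517), stood at 13.9 ± 3.81 CPM in CPUO and 61.3 ± 11.7 CPM in HC blood (log2 fold change -2.12, SE 0.26, n = 4 each). Its adjusted p was 0.130 by edgeR, the smallest of all classes, 0.00547 with the block as a covariate and 1.56e-07 by DESeq2. PER1, a clock gene induced by glucocorticoids, had a log2 fold change of 2.62 (SE 0.41) in the same cells and 2.81 (SE 0.48) in the B lineage. In CD4 T cells ZBTB10, a zinc finger repressor (chromosome 8, 80485619 to 80526265), stood at 37.3 ± 8.45 and 10.8 ± 2.49 CPM (1.80, SE 0.25), and DUSP2, a MAP kinase phosphatase (chromosome 2, 96143166 to 96145440), at 41.1 ± 15.7 and 8.79 ± 2.12 CPM (2.23, SE 0.32). IKZF2, a regulatory T cell factor, stood lower in CPUO CD4 T cells (-1.41, SE 0.31). The cluster of CD4 T cells led by FOXP3, IL2RA and IKZF2 itself, examined after these values were seen, made up 4.55% ± 0.959 of CPUO and 8.21% ± 1.06 of HC CD4 T cells (SD, n = 4 each, exact permutation p = 0.0286). NR4A2 had a log2 fold change of 2.69 (SE 0.52) in CD8 T cells. In NK cells ARRDC3, an arrestin-like protein, had a log2 fold change of 1.61 (SE 0.27) and TKTL1, a transketolase-like protein, one of -1.86 (SE 0.32). In the B lineage ANK2, an ankyrin, had a log2 fold change of -2.12 (SE 0.35). None of these passed with edgeR without the block: the adjusted p was 0.493 for ZBTB10 and for DUSP2, 0.883 for NR4A2, 0.770 for ARRDC3 and for TKTL1, and 0.662 for PER1 and for ANK2 in the B lineage. With the block as a covariate, the adjusted p by edgeR was 0.0241 for ZBTB10 and 0.0247 for DUSP2 in CD4 T cells. It was 0.0104 for PER1 in innate-like T cells, and 0 genes were called that way in CD8 T cells, NK cells and the B lineage. IL4R, the shared receptor of IL-4 and IL-13, lay between -0.44 and -0.11 on the log2 scale in the 8 classes, with an adjusted p of 0.733 or more.

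By edgeR, 0 genes passed in each of the 8 classes. The count at an unadjusted p under 0.05 was 851 of 14354 tested in CD4 T cells (523 higher, 328 lower), 599 of 13350 (345 higher, 254 lower) in CD8 T cells, 746 of 13124 (389 higher, 357 lower) in NK cells and 778 of 9902 (417 higher, 361 lower) in innate-like T cells. It was 631 of 11008 (285 higher, 346 lower) in the B lineage, 644 of 12434 (403 higher, 241 lower) in classical monocytes, 434 of 9239 (211 higher, 223 lower) in non-classical monocytes and 473 of 8769 (242 higher, 231 lower) in dendritic cells. DESeq2 called 190 genes over the classes (166 higher, 24 lower), and edgeR with the block as a covariate called 79 (69 higher, 10 lower), of which DESeq2 shared 51. Of the 79 calls with that covariate, 21 were immediate early genes and 6 were NF-kB genes.

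Gene lists ask whether known programmes moved together. Immediate early genes, which cells transcribe within minutes of a stimulus, were higher in CPUO in each of the 8 classes tested, with median log2 fold changes of 0.57 in non-classical monocytes to 1.55 in innate-like T cells. In classical monocytes all 30 measured members were higher, with ATF3 at 156 ± 103 CPM in CPUO and 23.9 ± 8.05 CPM in HC blood (2.72, SE 0.48, n = 4 each) and CD69 at 3.10 (SE 0.49). T and NK transcripts were higher in these monocytes too, as given below, and whether lymphocyte RNA adds to the CD69 value was not tested. In CD4 T cells 25 of 27 members were higher, with JUNB at 2.31 (SE 0.43) and NR4A2 at 2.86 (SE 0.54). FOS, a subunit of AP-1, had a log2 fold change of 2.64 (SE 0.65) in the B lineage. The mean score of the list over the 8 classes was 7.17 ± 0.350 log2 CPM in CPUO and 5.94 ± 0.713 in HC blood (SD, n = 4 each), without overlap (exact permutation p = 0.0286, and 0.0333 within the blocks). The scores were 7.10 and 6.53 in the 8.0.1 block, a difference of 0.57, and 7.37 and 5.34 in the 9.0.1 block, a difference of 2.02. Camera passed the list in all 8 classes with its preset correlation, and in none with an estimated one (adjusted p = 0.452 to 0.464 with an estimated correlation). Over all genes no member passed. Adjusted over the list alone, 13 of 27 members passed in CD4 T cells, 10 of 27 in CD8 T cells, 11 of 26 in NK cells, 11 of 23 in innate-like T cells, 7 of 25 in the B lineage, 11 of 30 in classical monocytes, 2 of 27 in non-classical monocytes and 6 of 28 in dendritic cells. Without each library the list passed in all 8, with medians in non-classical monocytes of 0.24 without HC 3, 0.28 without HC 4 and 0.92 without HC 1, and of 1.28 in the B lineage without HC 2. Within the 8.0.1 block alone, 7 of the 8 classes passed, all but non-classical monocytes. The 9.0.1 block has 1 CPUO library, so no list was tested in it.

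**Figure D3:**
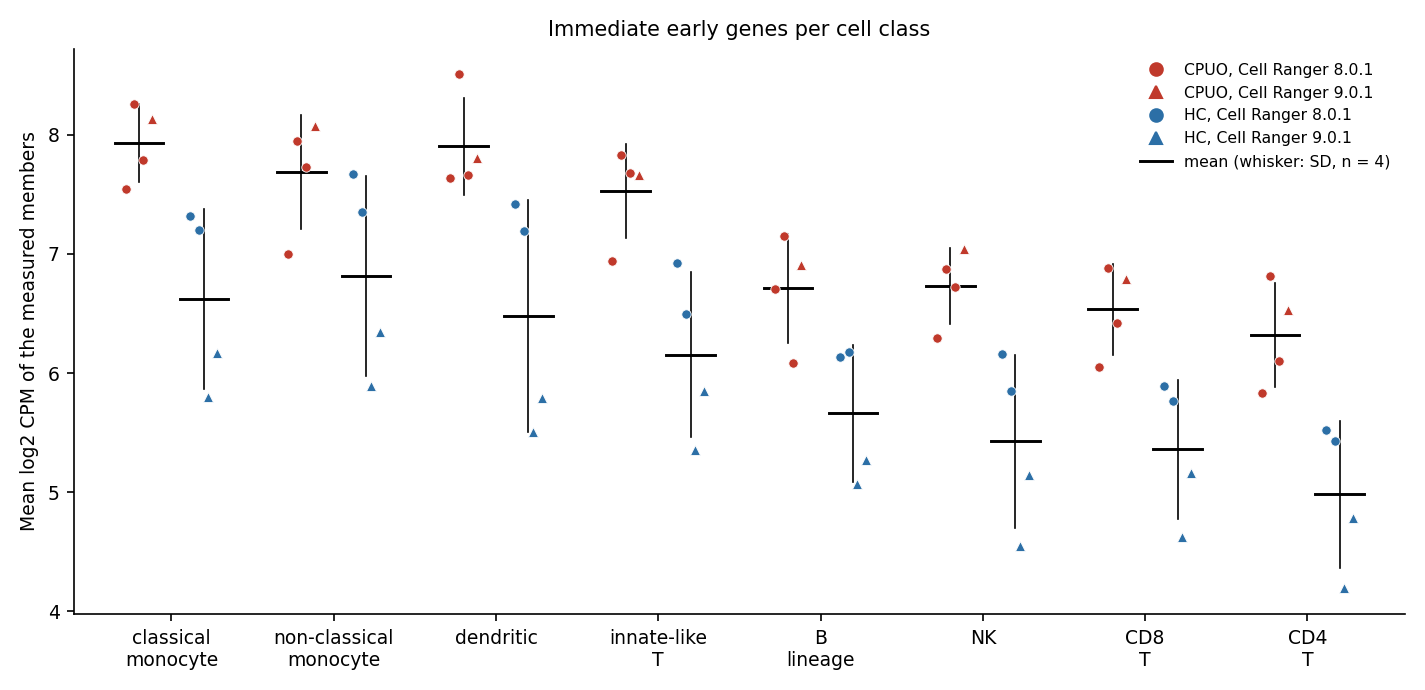
Mean log2 CPM of the measured immediate early genes (y axis) per library and cell class (x axis), with 1 point per library, red for CPUO and blue for HC, circles and triangles for the Cell Ranger version, bars for the mean and whiskers for the SD (n = 4). The groups lie apart in 6 of the 8 classes, all but the B lineage and non-classical monocytes, and chance alone separates 2.86% of such scores. The scores of the 8 classes come from the same libraries and are not independent, so the 6 cannot be weighed against that share.

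NF-kB and TNF response genes, which drive inflammation, passed as higher in all 8 classes, with medians of 0.26 to 1.03 (adjusted p = 0.452 to 0.464 with an estimated correlation). In classical monocytes 30 of 31 members were higher and 10 passed when adjusted over the list alone. Among them PTGS2, the inducible cyclooxygenase, had a log2 fold change of 2.42 (SE 0.51). TNFAIP3, the A20 inhibitor of NF-kB, stood at 2.41 (SE 0.62) in CD4 T cells, where 5 of 26 members passed by the same measure. TNF itself was at 1.34 (SE 0.60) in classical monocytes and 0.28 (SE 0.32) in CD4 T cells. The list passed in all 8 classes within the 8.0.1 block too. Without CPUO 4 it no longer passed in CD8 T cells (median 0.14), innate-like T cells (0.27) and the B lineage (0.33). The median was also 0.32 without CPUO 4 in non-classical monocytes, 0.46 without CPUO 2 and 1.205 without HC 1 in dendritic cells, 0.25 without HC 3 in the B lineage and 0.44 without CPUO 1 in CD8 T cells.

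Inflammatory chemokines passed as higher in 4 of 7 classes tested: classical monocytes (median 2.42, 9 of 10 higher), non-classical monocytes (1.65, 6 of 6), dendritic cells (1.57, 6 of 6) and CD4 T cells (0.80, 5 of 5). The list passed in these 4 without each library, but without CPUO 2 the median was 1.26 in classical monocytes, 0.67 in dendritic cells and 0.42 in CD4 T cells, where it was also 0.42 without HC 4 and 1.33 without HC 2. The smallest of their values was an adjusted p = 0.452 with an estimated correlation. Adjusted over the list alone, 6 members passed in classical monocytes, 1 in dendritic cells, and 0 in CD4 T cells and in non-classical monocytes. CCL4, a chemokine related to CCL3, had a log2 fold change of 4.30 (SE 1.41) in classical monocytes with overlapping groups, and 0.24 (SE 0.22) in NK cells. CCL3L3, a near-identical copy of CCL3 whose reads can be hard to tell apart from it, had one of 2.74 (SE 0.92) in classical monocytes and -1.30 (SE 0.92) in NK cells. In the same classical monocytes, T and NK transcripts were higher as well (median 1.68, 12 of 12 higher, adjusted p = 0.464 with an estimated correlation), with NKG7 at 78.9 CPM in CPUO and 25.1 CPM in HC blood. Cytotoxic effector genes moved with them there (median 1.67, 19 of 21 higher), as did naive T cell genes (0.53, 13 of 18 higher), with an adjusted p of 0.464 and 0.452 with an estimated correlation. In non-classical monocytes, T and NK transcripts (0.71, 10 of 10 higher) and cytotoxic genes (0.84, 14 of 17 higher) passed too, with an adjusted p of 0.490 and 0.544 with an estimated correlation. Without CPUO 2 the medians were 1.04 for cytotoxic and 0.28 for naive T cell genes in classical monocytes, and 0.35 for T and NK and 0.37 for cytotoxic genes in non-classical monocytes. Within the 8.0.1 block, the chemokine list passed as higher in classical monocytes and dendritic cells and as lower in innate-like T cells.

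Ribosomal protein genes passed as higher in all 8 classes by small amounts (medians 0.25 to 0.48, adjusted p = 0.464 to 0.657 with an estimated correlation), with RPS27 at 0.92 (SE 0.26) in CD4 T cells. Glucocorticoid response genes also passed in all 8 classes (medians 0.15 to 0.53, adjusted p = 0.452 to 0.582 with an estimated correlation). Their leading members were PER1 and DUSP1, while FKBP5, a classic glucocorticoid target, was at -0.16 (SE 0.55) in CD4 T cells and -0.46 (SE 0.58) in classical monocytes. Leaving out each library, ribosomal genes passed in all 8 classes each time, with medians of 0.13 (classical monocytes without CPUO 3) to 0.67 (CD8 T cells without HC 2). Glucocorticoid genes no longer passed without CPUO 4 in CD8 T cells (median 0.25), the B lineage (-0.10), classical monocytes (0.18) and non-classical monocytes (0.12), without HC 2 in NK cells (0.18) and the B lineage (0.05), or without HC 4 in the B lineage (0.08). Where they still passed, their median moved without HC 1 to 0.63 in CD4 T cells, 1.02 in CD8 T cells, 0.76 in NK cells, 0.90 in the B lineage and 0.90 in non-classical monocytes, and without HC 4 to 0.12 in CD4 T cells and 0.09 in classical monocytes. It also moved to 0.19 in dendritic cells without HC 3, 0.23 in CD8 T cells without CPUO 3, 0.21 in NK cells without CPUO 4, 0.76 in innate-like T cells without CPUO 2 and 0.25 in classical monocytes without CPUO 1. In the B lineage it was 0.01, 0.35 and 0.40 without CPUO 1, CPUO 2 and CPUO 3. Ribosomal genes passed in 4 classes within the 8.0.1 block and glucocorticoid genes in 1, the innate-like T cells. Interferon response genes passed as lower in classical monocytes (median -0.25, 40 of 52 lower), non-classical monocytes (-0.20, 37 of 50) and dendritic cells (-0.22, 34 of 47), with OAS1, an antiviral synthetase, at -0.75 (SE 0.25) in classical monocytes. With an estimated correlation the adjusted p was 0.591 to 0.657 for these. Without CPUO 4 the interferon list passed in none of these 3 classes (medians -0.007, -0.10 and -0.065), and without HC 2 it did not pass in non-classical monocytes (-0.13). The interferon list passed as lower within the 8.0.1 block in non-classical monocytes and innate-like T cells. Monocyte transcripts passed as lower in non-classical monocytes (median -0.86, CD36 at -1.65, SE 0.43) and dendritic cells (-0.22, CD14 at -1.06, SE 0.31), with an adjusted p of 0.368 and 0.464 with an estimated correlation, and without CPUO 4 they did not pass in dendritic cells (-0.22).

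With all libraries, the itch mediator and type 2 list passed in no class (medians -0.22 to 0.19), and within the 8.0.1 block it passed as higher in 4, the NK cells, innate-like T cells, B lineage and classical monocytes (adjusted p by limma 0.00884 to 0.0467). With all libraries, 2 of its 14 members passed in classical monocytes when adjusted over the list alone, OSM at 5.14 (SE 0.88) and IL7R, which also marks T cells, at 1.84 (SE 0.45). Over the 179 tests of a list in a class, camera passed 70 with its preset correlation (62 higher, 8 lower), 0 with an estimated correlation (smallest adjusted p = 0.368), and fry passed 0 (smallest adjusted p = 0.0787).

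**Figure D4:**
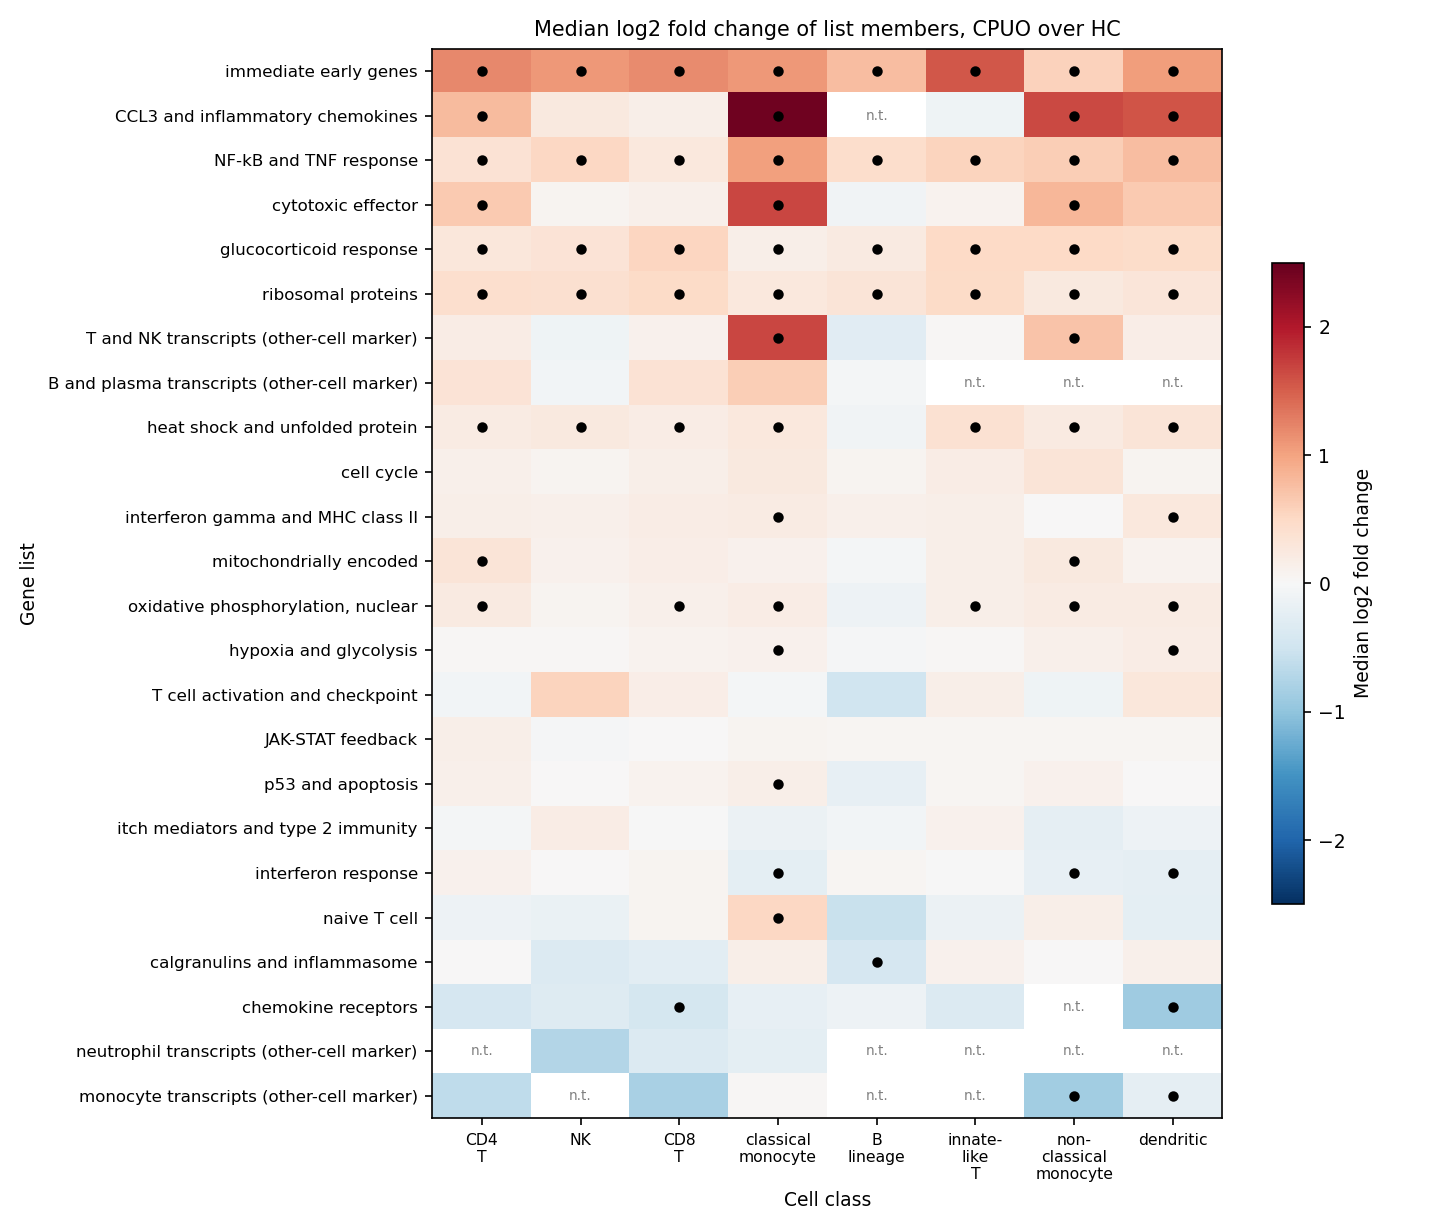
Median log2 fold change (CPUO over HC, color) of the measured members of 24 gene lists (y axis) in 8 cell classes (x axis), with a dot where camera passed with its preset correlation and n.t. where a list was not tested. Immediate early, NF-kB, glucocorticoid and ribosomal lists carry dots in all 8 classes, and none of the 70 dots holds with an estimated correlation.

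Whole libraries describe the blood preparation and move with the class shares. All 13 measured platelet transcripts were lower in CPUO blood (median -2.62), each at an unadjusted p under 0.05, with TREML1, a platelet receptor, at 0.489 CPM in CPUO and 5.12 CPM in HC blood (-3.38, SE 0.55). All 10 monocyte transcripts were lower (median -1.56), as 24 of 26 calgranulin and inflammasome genes were (median -0.75). All 12 T and NK transcripts were higher (median 0.47), as were 23 of 26 cytotoxic effector genes (median 0.90). DUSP2 stood at 114 CPM in CPUO and 26.7 CPM in HC blood (2.10, SE 0.32, adjusted p = 0.515). Of 5 red cell transcripts measured, 4 were higher and none had an unadjusted p under 0.05. By edgeR 0 of 20505 genes passed, 1785 had an unadjusted p under 0.05 (722 higher, 1063 lower), DESeq2 called 179 (79 higher, 100 lower), and edgeR with the block as a covariate called 25 (6 higher, 19 lower), TREML1 and DUSP2 among them.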

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

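Of the tests in this part, those of the processing block, of the UMI floor, of sample handling, of NK cells among other cells, of the regrouped libraries for gene counts and of regrouping within the blocks were chosen only after the result was seen; those of NK RNA and of the regrouped libraries for lists were written before it.

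In 6 of the 60 groups of 4 libraries examined, 1 library lay far from the other 3, where chance gives about 1 in 20. CPUO 4 held 49850000 UMIs, against 40310000 to 41120000 in the other CPUO libraries. NK cells made up 20.6% of classed cells in HC 2 (95% exact interval 19.7% to 21.4%), against 11.6% to 12.7% in the other HC libraries. Innate-like T cells made up 12.2% in CPUO 3 (95% exact interval 11.5% to 12.9%), against 3.33% to 4.73% in the other CPUO libraries. CCL3 in classical monocytes stood at 1961 CPM in CPUO 2, against 121.6 to 418.3 CPM in the other CPUO libraries. CCL3 in non-classical monocytes stood at 51.1 CPM in CPUO 4, against 14.6 to 20.1 CPM, and CCL3 in dendritic cells at 9.05 CPM in HC 3, against 24.5 to 27.2 CPM in the other HC libraries.

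Immediate early genes were higher in CPUO libraries, by 1.23 log2 CPM in the mean score over 8 classes, with 0.57 in the 8.0.1 block and 2.02 in the 9.0.1 block. The processing block as the whole cause is argued against by the scores within each block. In the 8.0.1 block they were 6.749, 7.532 and 7.024 in CPUO and 6.631 and 6.432 in HC libraries. In the 9.0.1 block they were 7.366 in CPUO and 5.123 and 5.565 in HC libraries. The exact permutation p of 0.0333 within the blocks, the smallest that they allow, follows from the groups lying apart over all libraries and adds nothing to this. The UMI floor of CPUO 1 and CPUO 2 is argued against by the difference of 1.13 that remained with 1 common floor in all libraries. Handling of the blood before lysis, which can start this response in every cell, stays open, since the score in the B lineage gave an exact permutation p of 0.0857, and it cannot be told apart from the disease itself here. A response to the disease may add to it, and that remains an untested hypothesis.

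Fewer classical monocytes and platelets and more NK cells were found in CPUO libraries. For classical monocytes, the UMI floor of CPUO 1 and CPUO 2 is argued against by the difference in their share, which was -14.0 percentage points with a common floor (7.93% and 21.9%). Platelets, with a median of 2622 UMIs, lie nearer to that floor. Yet CPUO 3 and CPUO 4, whose barcodes start at 502 and 500 UMIs, held 0.178% and 0.130% platelets, against 0.627% to 1.60% in HC libraries. This argues against the floor as the whole cause for platelets. For NK cells the direction of the difference held with the common floor, but its size is not given here, so the floor stays open there. The processing block as the whole cause is argued against for the libraries of the 8.0.1 block, where the difference in this share was -18.9 percentage points (CPUO 1.17%, 3.22% and 8.12%, HC 26.0% and 20.2%), but it stays open over both blocks, with an exact permutation p of 0.0667 within them and 15.2% in CPUO against 14.4% and 15.7% in HC libraries of the 9.0.1 block. Whether the NK share is higher only because monocytes and platelets are fewer stays open too: among the other cells NK cells made up 28.5% ± 7.29 and 18.7% ± 6.57 (SD, n = 4 each, exact permutation p = 0.0571). A difference of the disease may add to these shares, and it was not tested apart from them.

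CCL3 was higher in CPUO classical monocytes. RNA of NK cells in monocyte droplets is argued against, since NK RNA scaled by GNLY, an abundant NK transcript, gives at most 1.68% of the CCL3 in any CPUO library. The processing block as the whole cause is argued against by the CCL3 levels within each block. In the block that holds CPUO 2 they were 121.62, 1961 and 169.73 CPM in CPUO and 82.51 and 92.93 CPM in HC libraries. In the other block they were 418.27 CPM in its only CPUO library and 21.72 and 62.45 CPM in HC libraries. The exact permutation p of 0.0333 within the blocks follows from the groups lying apart over all libraries and adds nothing to this. Handling before lysis was not tested apart for CCL3 and stays open, as does the disease. The size may rest largely on CPUO 2, without which the log2 fold change was 1.87.

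With 0 genes by edgeR in the real split, all 35 of the 35 splits of the 8 libraries into groups of 4 give as many by construction, so these counts say nothing about chance. The highest count of another split was 2412 in CD4 T cells, 1980 in CD8 T cells, 1842 in NK cells, 1626 in innate-like T cells, 1407 in the B lineage, 3366 in classical monocytes, 1491 in non-classical monocytes, 1338 in dendritic cells and 2552 in whole libraries. Each of these 9 highest splits set 4 libraries of the 8.0.1 block against its remaining library with the 9.0.1 block, which points to a structure of the samples along the block. With the block as a covariate, 79 genes were called over the classes and 25 in whole libraries, and in the 30 splits within the blocks the highest other counts were 40 and 1. Only the real split, 1 of 30, reached each of these counts. That is the smallest share these splits allow, and the test was chosen after the result was seen. Chance as their whole cause is thus made less likely but is not excluded. For the lists, 8 of 35 splits gave as many as the 70 of the real split, with 86 as the highest other, so chance could not be excluded. With the block as a covariate, 3 of the 30 splits within the blocks gave as many as the 71 lists of the real split, with 84 as the highest other, so it could not be excluded there either. Immediate early genes passed in all 8 classes in 9 of the 35 splits and in 14 of the 30 splits within the blocks, the real one included, and ribosomal proteins in 12 and 10.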

How the results depend on the processing

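Of the alternatives here, the common UMI floor, the 8.0.1 block alone, the libraries without CPUO 1 and CPUO 2, and the replicate block with an estimated correlation were chosen after the data were seen. Of the values that answer a comparison, 335 kept their direction and their side of the threshold. For counts of genes and of lists this means a count near that of the main fit. Of the others, 615 kept both and 56 passed under an alternative only. Of the rest, each is given below, and the cause was not tested. No class share and no CCL3 value over all genes passed to begin with. The side kept for these was thus that of not passing. Over the 8 classes, edgeR called 0 genes, against 79 with the block as a covariate, 80 with no filter on low counts, 190 by DESeq2, 48 in the 8.0.1 block alone (14 higher, 34 lower, 45 of them in the B lineage), and 0 to 1 when each library was left out. It called 0 with RLE size factors, doublets kept, the stricter cell filter, clusters without correction, the common floor, and without CPUO 1 and CPUO 2. The 1 call came without CPUO 4, for ENSG00000273345 in innate-like T cells, a gene chosen after its values were seen. In whole libraries, against 0 genes, there were 25 with the block as a covariate, 179 by DESeq2 and 466 in the 8.0.1 block alone (48 higher, 418 lower). Of the 70 list calls, 0 held with an estimated correlation and 0 with fry. When each library was left out, 66 to 82 calls were made in total, which were not all the same calls. Calls that held without each library were 8 of 8 for immediate early and for ribosomal genes and 5 of 8 for NF-kB genes. They were 3 of 8 for glucocorticoid, 2 of 7 for heat shock and 0 of 3 for interferon response genes. Leaving each library out, the CCL3 log2 fold change was 1.87 to 3.72 in classical monocytes and 1.94 to 3.44 in dendritic cells, both lowest without CPUO 2. Likewise the share differences were -14.9 to -9.84 points for classical monocytes, 9.44 to 15.1 for NK cells, -0.846 to -0.523 for platelets, and, against -6.01 with all libraries, -10.8 (without HC 2) to -1.45 (without HC 4) for CD4 T cells, with -3.14 without CPUO 2. Other shares also moved, that of the B lineage from 0.724 to 1.64, 0.449 and 0.0240 without CPUO 1, 2 and 3 and to 0.245, 1.73 and 0.328 without HC 2, 3 and 4. That of CD8 T cells moved from 6.80 to 4.36 without CPUO 2 and that of non-classical monocytes from -1.69 to -0.932 without HC 2. That of dendritic cells moved from -0.357 to -0.128, -0.588 and -0.182, and of plasmacytoid dendritic cells from -0.114 to -0.0380, -0.261 and -0.0200, without CPUO 1, CPUO 4 and HC 1. CCL3 passed by DESeq2 in classical monocytes (3.35) and dendritic cells (3.14), and with no filter in dendritic cells (3.06). Without CPUO 1 and CPUO 2 it was -0.59 in CD8 T cells, and the share differences of dendritic (0.130 points) and plasmacytoid dendritic cells (0.0540) turned. Clusters without correction turned the B lineage (-7.21 points) and CD4 T cell shares (8.47). The innate-like T cell share difference, 1.73 with all libraries, ranged from -0.320 without CPUO 3 to 2.65 without CPUO 1, with 1.02 without HC 1. Platelets passed with edgeR on cell counts (-2.01). Thinned to 500 UMIs, the share of cells with a CCL3 UMI turned in innate-like T cells (0.0210 points) and the B lineage (-0.0130). Classical monocytes and innate-like T cells could not be tested without correction, nor innate-like T cells with doublets. The depth of 85 classical monocytes in CPUO 1 limits what that class can show.

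Whether the replicate numbers pair the samples is unknown. Deviations correlated at 0.618 to 0.823 in CD4 T cells for the numbers 1, 2 and 4, which each lie in 1 block and were positive in every class, and at -0.548 for the number 3, which spans both blocks, so these signs follow the block. With the replicate block, edgeR called 0 genes, and camera passed 76 lists, or 0 with an estimated correlation.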

Other observations

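The gene lists here were fixed before the data were examined, and the single genes called with the block as a covariate were picked after their values were seen.

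Heat shock and unfolded protein genes passed as higher in CPUO blood in 7 of 8 classes, all but the B lineage, with medians of 0.19 to 0.38 in those (adjusted p = 0.464 or more with an estimated correlation). All 28 measured members were higher in dendritic cells, while HSPA1A, the inducible HSP70, stood at -0.78 (SE 0.28) in CD4 T cells. The list passed as higher in 2 classes and as lower in 4 within the 8.0.1 block. With the block as a covariate it passed as higher in 6 classes, no longer in CD8 T cells (adjusted p by limma 0.136). Oxidative phosphorylation genes passed as higher in 6 classes (adjusted p = 0.657 or more with an estimated correlation), with ATP5ME, an ATP synthase subunit, at 0.62 (SE 0.21) in CD4 T cells, and within the 8.0.1 block they passed as higher in 4 classes and lower in 2. With the block as a covariate they passed as higher in 4 classes, no longer in CD8 T (adjusted p by limma 0.446) and innate-like T cells (0.247). In the B lineage they then passed as lower (0.0129). Mitochondrially encoded genes passed as higher in CD4 T cells and non-classical monocytes (adjusted p = 0.754 and 0.733 with an estimated correlation). With the block as a covariate they passed as higher in 0 classes (adjusted p by limma 0.0860 in CD4 T cells). Cytotoxic effector genes passed as higher in CD4 T cells too (23 of 26 higher, adjusted p = 0.700 with an estimated correlation), with IFNG at 2.35 (SE 0.54). Within the 8.0.1 block they passed as higher in 4 classes and as lower in CD8 T (adjusted p by limma 0.0285) and innate-like T cells (2.09e-07). Hypoxia genes, with BHLHE40 at 1.57 (SE 0.39) in classical monocytes, and interferon gamma and MHC class II genes, with IFI30 at 1.27 (SE 0.37) in dendritic cells, passed as higher in classical monocytes and dendritic cells. With the block as a covariate, interferon gamma genes no longer passed in classical monocytes (adjusted p by limma 0.196). With an estimated correlation the adjusted p was at least 0.452 for hypoxia and 0.668 for interferon gamma. The p53 list passed as higher in classical monocytes alone of 8 classes (adjusted p = 0.452 with an estimated correlation).

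Chemokine receptors passed as lower in CD8 T cells (9 of 10 lower) and dendritic cells (4 of 5 lower), with an adjusted p of 0.452 and 0.464 with an estimated correlation. In CD8 T cells CXCR3 stood at -1.13 (SE 0.27) and CXCR6, a tissue-homing receptor, at -2.21 (SE 0.62), and both passed when adjusted over the list alone. In dendritic cells CCR1 (-1.10, SE 0.30) and CCR2 (-0.89, SE 0.35) were lower and CXCR4 (2.17, SE 0.58) was higher, and these 3 passed by the same measure. With all libraries, calgranulin and inflammasome genes passed as lower in the B lineage alone of 8 classes (adjusted p = 0.464 with an estimated correlation). Within the 8.0.1 block they passed as lower in 4, and with the block as a covariate in CD8 T cells, NK cells and the B lineage. There S100A8 (-2.68, SE 0.69) and S100A9 (-1.78, SE 0.47), abundant transcripts of monocytes, were the leading members. T cell activation, JAK-STAT feedback, cell cycle, neutrophil, and B and plasma transcripts passed in no class with all libraries. Within the 8.0.1 block, T cell activation passed as lower in CD4 T cells, JAK-STAT feedback as higher in CD4 T cells and the B lineage, and B and plasma transcripts as higher in classical monocytes. T cell activation passed as higher in NK cells with the block as a covariate. Their medians were -0.50 to 0.56 for T cell activation, -0.03 to 0.14 for JAK-STAT feedback, 0.06 to 0.33 for cell cycle, -0.73 to -0.24 for neutrophil, and -0.06 to 0.62 for B and plasma transcripts. With the block as a covariate, AREG, an EGF receptor ligand, was called in CD4 T cells (3.18, SE 0.46, adjusted p = 0.034), and KLRB1, a receptor of NK and T cells, in classical monocytes (2.53, SE 0.30, adjusted p = 0.0065). Cells with neutrophil markers numbered 0 to 4 per library.

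Many of these list calls ended when 1 library was left out, and the adjusted p by limma is given here for each. For heat shock and unfolded protein genes that was without HC 3 in CD4 T (0.314), CD8 T (0.710) and NK cells (0.237) and in classical (0.0643) and non-classical monocytes (0.0730). It was also without CPUO 4 in CD4 T (0.0864) and CD8 T cells (0.183), without HC 4 in CD8 T cells (0.117) and non-classical monocytes (0.0563), and without CPUO 3 in classical monocytes (0.113). For oxidative phosphorylation it was without HC 3 and HC 4 in turn in CD8 T cells (0.366 and 0.470) and innate-like T cells (0.0948 and 0.525), and without CPUO 3 in the latter (0.0665). For mitochondrially encoded genes it was without CPUO 2, CPUO 3 and HC 4 in turn in CD4 T cells (0.0847, 0.0990 and 0.615) and non-classical monocytes (0.194, 0.0614 and 0.856), and for cytotoxic genes without HC 4 in CD4 T cells (0.122). For chemokine receptors it was without CPUO 4, HC 1 and HC 2 in turn in CD8 T cells (0.0864, 0.0827 and 0.191) and dendritic cells (0.277, 0.0582 and 0.161), and for calgranulins without the same libraries in the B lineage (0.197, 0.106 and 0.104). For interferon gamma genes it was without CPUO 2, CPUO 3, HC 3 and HC 4 in turn in classical monocytes (0.154, 0.243, 0.314 and 0.172) and without CPUO 3 and HC 4 in dendritic cells (0.0841 and 0.0722). For hypoxia it was without CPUO 3, CPUO 4 and HC 3 in turn in classical monocytes (0.0783, 0.0980 and 0.0638) and without HC 3 in dendritic cells (0.149), and for p53 without CPUO 3 and CPUO 4 in classical monocytes (0.0983 and 0.150).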
